A study of Mus musculus with 6 samples.

How the data were processed

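The authors measured total RNA from the livers of 3 WT and 3 KO mice, extracted with Trizol, labelled with biotin and hybridised to Affymetrix mouse arrays, per the labels' protocols. The deposited values are log2 levels per probe set made with RMA (background correction, quantile normalization of probes and a summary per probe set), per the submitters' processing notes, which give no version. That the scale is log2 was read from the values, which run from 2.15 to 14.9 over the 6 arrays, with medians of 5.04 to 5.10. RMA forces the arrays towards one distribution, so a change that moves most transcripts one way is removed by it, and the levels are relative. No detection calls were used, and dim probe sets have compressed differences.

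Groups and replicate numbers come from the sample titles, and 1 array stands for 1 liver. Of 45101 probe sets, 64 are controls. The platform annotation of 2016 gives 34945 probe sets 1 gene symbol and 932 several, and 9160 are not listed in it and unnamed here. Symbols were checked through gene identifiers against the gene table of the mouse assembly GRCm38.p6, which changed 0 symbols, and 204 probe sets without a match kept their symbol. Probe sets with 1 symbol cover 18193 genes, each represented by its probe set of highest mean over all 6 arrays, and 53 genes had probe sets past the threshold in opposite directions. Of the 24 genes fixed in advance, 3 were not analysed here. Background was set at the 95th percentile (4.90) of the mean level of 38 olfactory receptor genes, which the liver should not express. Where all arrays of 1 group lay below it, the fold is a lower bound, computed with those arrays set to the background.

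Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options, group as the factor, two-sided) and adjusted by Benjamini-Hochberg over all 18193 genes, with a threshold of 0.05 and no filter. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 51 lists with at least 5 measured members, and with camera's estimated correlation, camera on ranks and fry beside it. Where no count adjusted over the list alone is given for one of these 51 lists, it equals the count over all genes. Controls were compared with exact two-sided permutation tests, for which 3 against 3 arrays cannot go below 0.1.

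The gene lists, the design, the alternatives and the rule for naming genes were fixed before the data were examined, except where a test is said to have been chosen later. The rule names the genes fixed in advance, the 10 largest rises and the 10 largest falls among changed genes whose KO arrays lie on one side of all WT arrays (without unnamed loci), and up to 4 changed members of each list with the largest difference. In lists without changed members it names up to 2. Alternatives were a replicate block, a filter that left 12128 genes, quantile normalization, centring on the array median, other choices of probe set, trend and robust eBayes, array weights, stricter thresholds and leaving out each array in turn. Centring on 38 bacterial control probe sets was added after the control values were seen.

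The fit was tested on simulated data with the spread of these arrays, 200 of 18193 genes being changed by known amounts. It recovered 22.7% of genes changed by 0.5 on the log2 scale, 76.4% of those changed by 1 and 95.2% of those changed by 2, with 4.6% false calls, so a gene without a call may still have changed by a small amount. The real comparison gave 4363 changed genes, for which the adjustment is less strict, and the simulated noise was independent between genes. These rates therefore need not hold for the real data. The number of arrays limits the precision.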

Results

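Transcript levels were measured on Affymetrix mouse expression arrays in the livers of 10-week-old male mice, 3 wild-type (WT) and 3 labelled as knockouts of Pex5 in the liver (KO), with 1 array per liver. Pex5 is the receptor that carries newly made enzymes into the matrix of peroxisomes, the organelles that shorten very-long-chain fatty acids and take part in making bile acids and ether lipids. The labels place both groups on a mixed background with Alb-Cre, a recombinase driven by the albumin promoter, which is active in hepatocytes. The labels call the arrays biological replicates and record no date or batch, and the liver pieces hold all liver cell types. Values are log2 levels, differences are KO minus WT, and errors are the SD over 3 livers or the SE of limma's fit. The number of arrays limits the precision. Over 18193 genes, arrays of one group correlated at r of at least 0.989 and arrays of different groups at no more than 0.976. The first principal component, with 73.6% of the variance, placed the 3 WT arrays between -41.9 and -31.9 and the 3 KO arrays between 33.2 and 40.9.

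The comparison asks what happens to transcription in the liver when hepatocytes lose functional peroxisomes, with the series title pointing to the energy sensor AMPK, the coactivator PGC-1alpha and the use of sugars. In KO livers, Ppargc1a, Pck1, Slc37a4, Slc2a2 and Gys2 were lower, while the lists of gluconeogenesis, glycogen, glycolysis and pentose phosphate genes held changes in both directions or few changes and did not pass camera. Lists of fatty acid oxidation, antioxidant, p53 target and cell cycle genes held more higher than lower genes, and lists of male-biased, bile acid and urea cycle genes more lower than higher ones. None of 51 lists passed camera with an estimated correlation, where the lowest adjusted p was 0.113. With the arrays centred on bacterial control transcripts, 9 bile acid genes were higher and 9 lower, and 10 urea cycle genes were higher and 8 lower. Of 18193 genes, 2589 were higher and 1774 lower in KO (limma, adjusted p under 0.05), so that 59.3% of the 4363 changed genes were higher. That share depends on the normalization, being 51.8% with quantile normalization and 66.2% with the arrays centred on the median. At least 2-fold differences were found in 550 of the higher and 327 of the lower genes, and at least 4-fold ones in 123 and 87. The 3 KO arrays lay wholly above or below the 3 WT arrays in 8143 genes (44.8%), against 10% by chance. The count of changed genes fell most when a KO array was left out. It was 2385 without KO replicate 2 and 2588 without KO replicate 1, against 3557 to 4103 without 1 WT array. The lower genes numbered 888, 984 and 1156 without KO replicates 2, 1 and 3. The KO arrays were the closer group (lowest r within the group 0.9946, against 0.9892 in WT), so these counts do not show that the differences rest on 1 KO liver. The bacterial control transcripts added to each sample were dimmer on the KO arrays, and centring the arrays on them raised the median difference over all genes by 0.51, from -0.055 to 0.46. It gave 12970 higher and 409 lower genes (96.9% higher), and each of those 409 was also lower as deposited. Directions below are therefore relative to the bulk of the genes, as the deposited values set it, and control centring adds the same 0.51 to each difference.

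The targeted transcript came first. Pex5 stood at 9.04 ± 0.14 in WT and 9.22 ± 0.11 in KO (SD, n = 3), a difference of 0.18 ± 0.11 (SE, adjusted p = 0.262), or 0.69 with the arrays centred on the bacterial controls (adjusted p = 0.000663). Its second probe set differed by 0.15 ± 0.13. The sources used here do not say whether either probe set covers the deleted part of the gene, so neither checks the labels. Ppargc1a, which encodes PGC-1alpha, a coactivator of gluconeogenic and mitochondrial genes, fell from 7.22 ± 0.19 to 5.5 ± 0.27, which is 3.30-fold lower (-1.72 ± 0.16, adjusted p = 0.000274). All 5 of its probe sets were lower, with differences from -0.94 to -1.72. Its relative Ppargc1b differed by -0.33 ± 0.14 (adjusted p = 0.133). Transcripts of AMPK, the kinase that responds to low cellular energy, moved by subunit: the regulatory subunit Prkab2 rose 2.25-fold (1.17 ± 0.11, adjusted p = 0.000362) and the catalytic subunit Prkaa2 1.49-fold (0.57 ± 0.12, adjusted p = 0.0115). The other catalytic subunit, Prkaa1, was higher by 0.42 ± 0.13 at the edge of the threshold (adjusted p = 0.0488, from 0.000781 to 0.149 over 15 alternatives). Its call was lost without WT replicate 1 or 3 (0.062 and 0.0634) or without KO replicate 1, 2 or 3 (0.116, 0.149 and 0.107), with quantile normalization (0.0556) and with trend and robust eBayes (0.0547). Prkab1 differed by 0.18, which passed at 0.69 with the arrays centred on the bacterial controls (adjusted p = 0.00502). Prkag1 and Prkag2 differed by -0.14 and -0.12, values that turned to 0.37 and 0.39 on that scale and passed there. As deposited, 1 of the 4 probe sets of Prkag2 passed as lower and 0 as higher. In the list of AMPK subunits, kinases and energy sensors, 4 of 16 measured genes were higher and 1 was lower (4 and 2 adjusted over the list alone). Camera, limma's test of a list against all other genes, did not pass (adjusted p = 0.475). In the list of the PGC-1alpha family and partners, 2 of 21 were higher and 4 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.911). Its median was -0.024, its mean 0.052 and the direction of its test down. The largest rise was that of Trib3, a pseudokinase that binds AKT (4.67 ± 0.34).

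**Figure D1:**
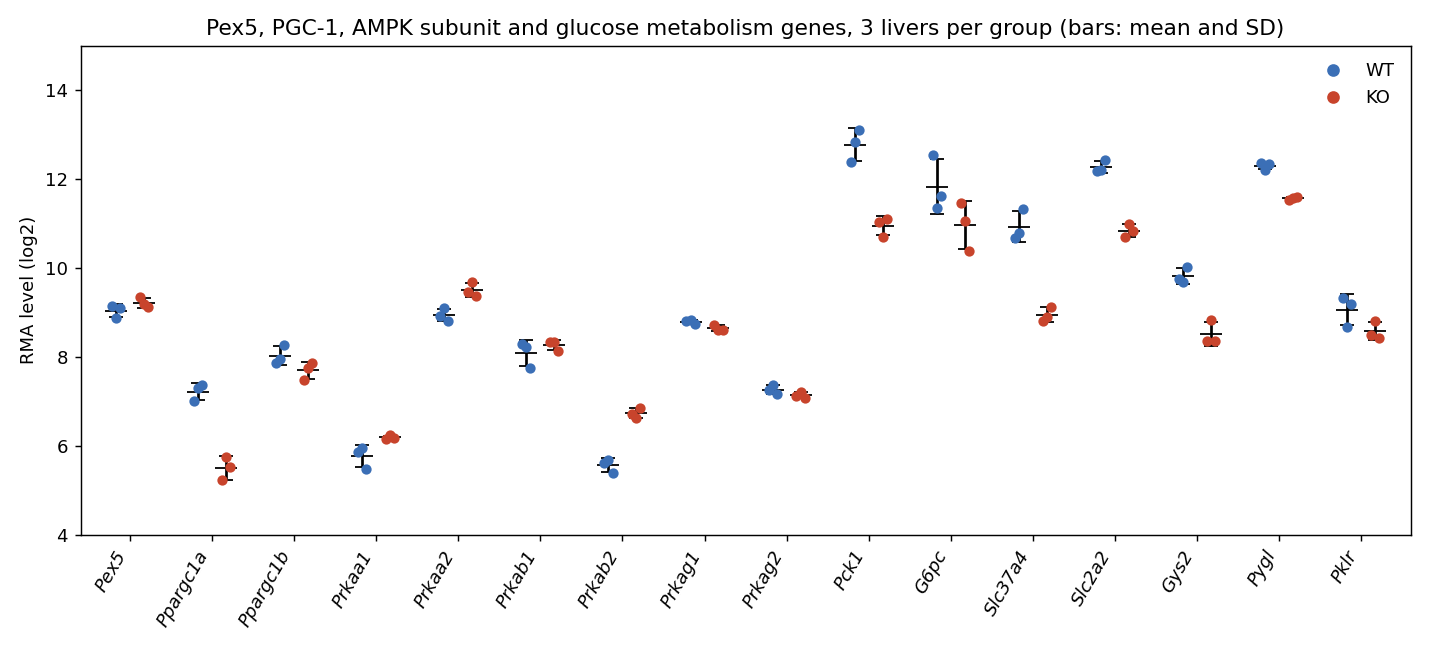
RMA level (log2, y axis) of Pex5, PGC-1, AMPK subunit and glucose metabolism genes (x axis) in 3 WT and 3 KO livers, with points for livers and bars for mean and SD. Ppargc1a stands at 7.22 in WT and 5.5 in KO and Pck1 at 12.78 and 10.96, while the groups overlap for Pex5 and G6pc; Prkag1 and Prkag2, slightly lower in KO here, turn higher with the arrays centred on the bacterial controls.

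Pck1, Slc37a4, Slc2a2, Gys2 and Pygl, which serve the release and storage of glucose, were lower. Pck1, which makes phosphoenolpyruvate for gluconeogenesis, fell 3.54-fold, from 12.78 ± 0.36 to 10.96 ± 0.22 (-1.83 ± 0.19, adjusted p = 0.000524). Slc37a4, the carrier of glucose 6-phosphate into the endoplasmic reticulum, fell 3.92-fold (-1.97 ± 0.18) and Slc2a2, the main glucose transporter of hepatocytes, 2.69-fold (-1.43 ± 0.12). G6pc, the catalytic subunit of glucose 6-phosphatase, stood at 11.83 ± 0.62 in WT and 10.97 ± 0.54 in KO and did not pass (adjusted p = 0.108, from 0.0256 to 0.33 over 15 alternatives). It passed as lower with a replicate block (adjusted p = 0.0256). Gys2, the liver glycogen synthase, fell 2.47-fold (-1.30 ± 0.15) and Pygl, the liver glycogen phosphorylase, 1.67-fold (-0.74 ± 0.09). With the arrays centred on the bacterial controls Pygl differed by -0.22 and lost its call (adjusted p = 0.0609). Of 18 measured genes of gluconeogenesis and glucose release 6 were lower and 4 higher (8 and 4 adjusted over the list alone), and camera did not pass (adjusted p = 0.494). The median of -0.21 was 0.30 with the arrays centred on the bacterial controls. Fbp2, the muscle form of fructose bisphosphatase, was among the higher ones (1.26 ± 0.21). In the glycogen list 5 of 21 genes were higher and 2 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.25), the largest rises being Pgm2 (1.58 ± 0.10) and the glycogen primer glycogenin, Gyg (1.43 ± 0.13). Among 24 glycolysis genes 4 were higher and 2 lower (4 and 4 adjusted over the list alone, camera adjusted p = 0.664), with Pfkp, the platelet form of phosphofructokinase, up 6.30-fold (2.66 ± 0.16) and Aldoa up 2.04-fold (1.03 ± 0.10). Pklr, the liver pyruvate kinase, differed by -0.48 ± 0.18 (adjusted p = 0.0897, from 0.0193 to 0.871 over 15 alternatives) and passed once WT replicate 2 was left out (-0.68, adjusted p = 0.0193). Hk2 differed by 0.31 ± 0.20 (adjusted p = 0.282, from 0.00637 to 0.569) and passed without WT replicate 1 (0.56, adjusted p = 0.0156) and with the arrays centred on the bacterial controls (0.82). In the pentose phosphate pathway 3 of 9 genes were higher and none lower (camera adjusted p = 0.385), including Pgd (1.49 ± 0.11) and Tkt (0.65 ± 0.10). Fructose, galactose and polyol genes were lower in 3 of 7 measured members and higher in none (camera adjusted p = 0.0128, and adjusted p = 0.252 with an estimated correlation). Their median of -0.53 was -0.017 with the arrays centred on the bacterial controls, where 1 was higher and 2 lower. Ketohexokinase, Khk, was lower (-1.14 ± 0.11), and so was the fructose transporter Slc2a5, from 6.38 ± 0.39 to 4.89 ± 0.27, a mean under the background of 4.90, so the size of its fall is not fixed.

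Lists of fatty acid oxidation held more higher than lower genes. Of 32 measured targets of PPARalpha, the fatty acid sensor of hepatocytes, outside peroxisomes, 21 were higher and 2 lower (camera adjusted p = 2.45e-08, and adjusted p = 0.113 with an estimated correlation). The microsomal fatty acid hydroxylase Cyp4a14 went from 5.96 ± 1.44 to 13.40 ± 0.03 (7.44 ± 0.60, adjusted p = 0.000138), the fatty acid translocase Cd36 rose by 4.92 ± 0.34, the thioesterase Acot1 by 4.59 ± 0.22, and Fgf21, a hormone of the fasting liver, by 4.43 ± 0.46. Pdk4, which inhibits pyruvate dehydrogenase, rose by 3.10 ± 0.68 (adjusted p = 0.0144, from 0.000125 to 0.0696 over 15 alternatives). Its call was lost without KO replicate 1 (adjusted p = 0.0563), without KO replicate 2 (0.0523) or with trend and robust eBayes (0.0696). The wide spread was that of WT, at 8.28, 5.70 and 5.35 in replicates 1, 2 and 3, against an SD of 0.39 in KO. Ppara itself differed by -0.37 ± 0.12 (adjusted p = 0.0522, from 0.00485 to 0.384), and passed as lower without WT replicate 3 (adjusted p = 0.0329) or KO replicate 3 (0.0447) and under 5 further alternatives. Centring on the bacterial controls, which adds 0.51, turns its sign. Peroxisomal beta-oxidation genes were higher in 13 of 21 and lower in 2 (3 lower adjusted over the list alone, camera adjusted p = 0.000188, and adjusted p = 0.255 with an estimated correlation). Among them Ehhadh, the bifunctional enzyme, rose 5.91-fold to 13.97 ± 0.07 and the thioesterases Acot3 and Acot4 by 4.27 ± 0.13 and 2.42 ± 0.22. Of 12 peroxisome biogenesis genes 3 were higher (camera adjusted p = 0.133), with Pex11a, which drives peroxisome division, up 3.62-fold. Other peroxisomal enzymes were lower in 7 of 24 and higher in 1 (camera adjusted p = 0.385), among them the glyoxylate-handling enzymes Hao1 (-2.09 ± 0.22) and Agxt (-1.13 ± 0.17). In mitochondria, 9 of 17 beta-oxidation genes were higher and none lower (10 higher adjusted over the list alone, camera adjusted p = 1.11e-05, and adjusted p = 0.37 with an estimated correlation), with Decr1, Eci1 and Hadhb up 2.28-fold, 2.24-fold and 2.07-fold.

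In the list of pyruvate dehydrogenase and the TCA cycle 7 of 28 genes were higher and 2 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.0355, and adjusted p = 0.766 with an estimated correlation), with Mdh2 up 2.09-fold and Idh2 1.79-fold. That call was lost without WT replicate 1 (adjusted p = 0.0532), WT replicate 3 (0.0507), KO replicate 1 (0.106) or KO replicate 2 (0.074), and over 18 alternatives its adjusted p ran from 0.00766 to 0.766. Mitochondrial biogenesis and dynamics genes were higher in 8 of 26 and lower in 1 (9 higher adjusted over the list alone, camera adjusted p = 0.000408, and adjusted p = 0.286 with an estimated correlation), with the protease Lonp1 higher by 1.77 ± 0.11. The import receptor Tomm20 was higher by 0.93 ± 0.13 in its brightest probe set, and of its 6 probe sets 4 were higher and 1 was lower. For respiratory complex I 3 of 33 genes were higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.374). For complexes III and IV with cytochrome c 1 of 20 was higher (none adjusted over the list alone, camera adjusted p = 0.0564, from 0.0166 to 0.647 over 18 alternatives), and camera passed without WT replicate 3 (0.0407) or KO replicate 3 (0.0367). For ATP synthase 1 of 16 was higher (camera adjusted p = 0.682), with a median of -0.017 and a mean of 0.062.

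Lipid synthesis genes went both ways. Srebf1, the driver of lipogenic genes, fell 2.18-fold (-1.13 ± 0.19, adjusted p = 0.00511). Srebf2, its counterpart for cholesterol synthesis, fell by 0.49 ± 0.11 (adjusted p = 0.0147, from 0.00727 to 0.853 over 15 alternatives), a call lost without KO replicate 2 (adjusted p = 0.0552) or with the mean of its probe sets (-0.20, adjusted p = 0.219) and a value that turned to 0.03 with the arrays centred on the bacterial controls. Of 26 genes of fatty acid and triglyceride synthesis 4 were higher and 4 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.911). Their median was 0.09, their mean -0.046 and the direction of their test up. Thrsp, a thyroid-responsive lipogenic protein, fell 7.56-fold, while malic enzyme Me1 rose 2.99-fold. Of 20 cholesterol synthesis and uptake genes 1 was higher and 1 lower (camera adjusted p = 0.911). Of 25 bile acid genes 12 were lower and 5 higher (13 lower adjusted over the list alone, camera adjusted p = 0.0155, and adjusted p = 0.252 with an estimated correlation). Their median of -0.58 was -0.072 with the arrays centred on the bacterial controls, where 9 were higher and 9 lower. The sterol hydroxylases Cyp8b1 and Cyp7b1 fell 8.44-fold and 6.53-fold and the sinusoidal uptake carrier Slco1a1 was also lower (-4.99 ± 0.68). Abcc4, an export pump of the sinusoidal membrane, rose at least 70.2-fold (adjusted p = 7.53e-07). Lipoprotein genes were lower in 8 of 19 and higher in 1 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0495, and adjusted p = 0.496 with an estimated correlation), their median of -0.31 turning to 0.21 with the arrays centred on the bacterial controls. Apoa4 fell 3.26-fold and the HDL receptor Scarb1 2.06-fold, and lipoprotein lipase, Lpl, rose 7.03-fold. The lipoprotein call was lost without WT replicate 1 (adjusted p = 0.0992), WT replicate 3 (0.0515) or KO replicate 2 (0.0698), and ran from 0.00243 to 0.496 over 18 alternatives.

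Antioxidant, p53 target and cell cycle lists held more higher than lower genes. Of 27 antioxidant genes and NRF2 targets 12 were higher and 1 lower (16 higher adjusted over the list alone, camera adjusted p = 2.41e-06, and adjusted p = 0.113 with an estimated correlation), with the quinone reductase Nqo1 up 6.92-fold, sulfiredoxin Srxn1 6.44-fold and the glutathione peroxidase Gpx3 7.78-fold. Of 16 p53 targets and DNA damage genes 11 were higher and 1 lower (camera adjusted p = 3.46e-06, and adjusted p = 0.113 with an estimated correlation), among them Gadd45a (2.95 ± 0.37) and the cell cycle inhibitor Cdkn1a (1.86 ± 0.21). Of 29 cell cycle genes 16 were higher and 1 lower (21 and 3 adjusted over the list alone, camera adjusted p = 3.78e-06, and adjusted p = 0.244 with an estimated correlation). Cyclin D1, Ccnd1, rose 3.61-fold. The proliferation marker Mki67 was higher, at 4.81 ± 0.18 in WT, a mean under background, and 6.30 ± 0.61 in KO, so the size of its rise is not fixed. Cytosolic ribosomal protein genes were higher in 17 of 29 and lower in none (19 and 1 adjusted over the list alone, camera adjusted p = 4.47e-07, and adjusted p = 0.479 with an estimated correlation), with a median of 0.33. Rpl35 rose 1.69-fold. Lysosome and autophagy genes were higher in 11 of 23 and lower in 2 (12 and 3 adjusted over the list alone, camera adjusted p = 0.00512, and adjusted p = 0.255 with an estimated correlation), led by the autophagy receptor Sqstm1 and cathepsin Ctsl (2.38-fold and 2.10-fold). Endoplasmic reticulum stress genes went both ways, 9 of 26 higher and 7 lower (10 and 9 adjusted over the list alone, camera adjusted p = 0.75): the transcription factors Atf3 and Ddit3 rose 10.09-fold and 5.18-fold, and the chaperone component Sdf2l1 fell 4.66-fold. Of 15 fetal liver and liver tumour genes 5 were higher and 1 lower, including Ly6d (6.37 ± 0.16) and alpha-fetoprotein, Afp. Camera gave an adjusted p of 0.094, and 0.0223 without KO replicate 1. Over 18 alternatives the adjusted p ran from 0.00146, which was that of fry, to 0.363, that of camera with an estimated correlation. Afp stood at 4.35 ± 1.23 in WT, a mean under the background of 4.90, and at 10.54 ± 0.50 in KO, so the size of its rise is not fixed by these arrays.

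Transcripts that set male from female livers apart changed in both directions. Of 14 measured male-biased genes 12 were lower and none higher, with a median of -2.65 (camera adjusted p = 4.13e-09, and adjusted p = 0.244 with an estimated correlation). The steroid dehydrogenase Hsd3b5 fell from 11.88 ± 0.17 to 5.04 ± 0.58 (-6.84 ± 0.26, adjusted p = 6.66e-06), Slco1a1 from 11.62 ± 0.46 to 6.63 ± 1.57, and Serpina12 from 9.65 ± 1.70 to 4.86 ± 0.33, a mean under background. Of 20 female-biased genes 10 were higher and 1 lower (camera adjusted p = 0.000303, and adjusted p = 0.383 with an estimated correlation), among them the cytochrome P450 genes Cyp2b9 (4.94 ± 0.55) and Cyp2b10 (4.02 ± 0.37), the peroxisomal oxidase Hao2 (4.28 ± 0.21) and Acot3. The female-biased list shares 3 measured genes with peroxisomal beta-oxidation, Acot3 and Acot4 among them, and the male-biased list shares 2 with the bile acid genes.

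**Figure D2:**
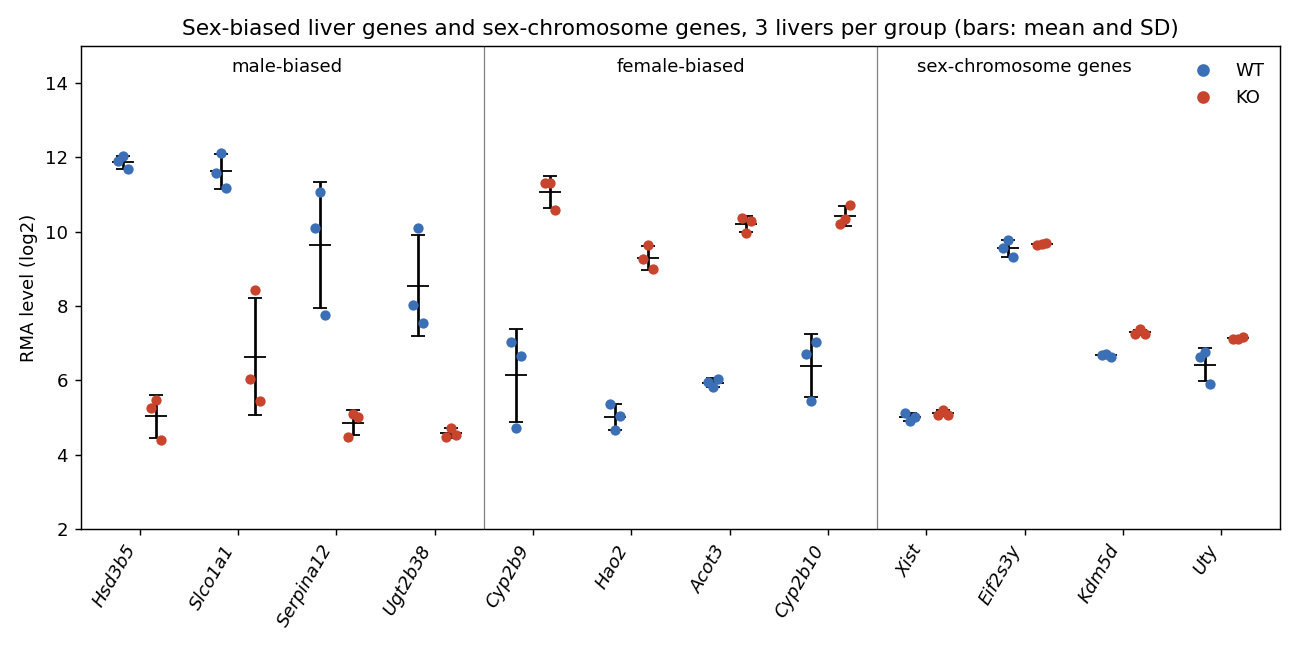
RMA level (log2, y axis) of 4 male-biased, 4 female-biased and 4 sex-chromosome genes (x axis) in 3 WT and 3 KO livers, with points for livers and bars for mean and SD. Hsd3b5 stands at 11.88 in WT and 5.04 in KO and Cyp2b9 at 6.13 and 11.07, while Xist stays near 5 in both groups and the Y-linked genes are not lower in KO.

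Several other hepatocyte lists held more lower than higher genes relative to the bulk of genes. Urea cycle and amino acid catabolism genes were lower in 22 of 34 and higher in 1 (23 and 2 adjusted over the list alone, camera adjusted p = 3.18e-07, and adjusted p = 0.244 with an estimated correlation), their median of -0.49 turning to 0.02 with the arrays centred on the bacterial controls. Otc, the urea cycle enzyme that makes citrulline, fell 4.08-fold to 10.63 ± 0.10, and the tryptophan-degrading enzymes Haao and Kmo were lower (-1.75 ± 0.17 and -1.32 ± 0.11). Xenobiotic P450 enzymes and regulators were lower in 12 of 25 and higher in 2 (16 and 4 adjusted over the list alone, camera adjusted p = 0.000185, and adjusted p = 0.252 with an estimated correlation), a median of -0.36 that turned to 0.16 on the control-centred scale. Cyp2c54 fell by 4.57 ± 0.29 and Cyp2c50 10.15-fold, and Cyp2b10 was an exception among them. Acute phase genes were lower in 12 of 22 and higher in 2 (13 and 3 adjusted over the list alone, camera adjusted p = 0.000955, and adjusted p = 0.636 with an estimated correlation). Their median of -0.95 was -0.44 with the arrays centred on the bacterial controls, where 5 were higher and 10 lower. Serum amyloid Saa1 was lower by 3.39 ± 0.54 and Apcs, serum amyloid P, higher by 2.18 ± 0.23. The hepatocyte identity list was lower in 8 of 21 genes and higher in 1 but did not pass (camera adjusted p = 0.0664), its median of -0.21 being 0.30 on the control-centred scale, and its largest fall was that of the nuclear receptor Nr1i3 (3.13-fold). It shares 3 measured genes with the urea cycle list.

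Ranked by measured log2 difference, the 10 largest rises outside unnamed loci were those of Cyp4a14, Nupr1, Abcc4, Ly6d, Afp, Tenm2, Psat1, Cbr3, Cyp2b9 and Cd36. Levels under background enter this ranking as measured, so places that rest on them are not fixed. Nupr1, a stress-induced nuclear protein, rose from 4.90 ± 0.21, at the background, to 11.67 ± 0.50. The carbonyl reductase Cbr3 rose by 5.07 ± 0.21, Tenm2 at least 17.6-fold and Psat1, an enzyme of serine synthesis, at least 24.3-fold, each of the last 2 being within background in WT. By the same ranking, the 10 largest falls were those of Hsd3b5, Serpina4-ps1, Mup10, Slco1a1, Serpina12, Cyp2d13, Cyp2c54, Wfdc21, Slco2b1 and Ugt2b38, the place of Ugt2b38 resting on levels under background in KO. The major urinary protein gene Mup10 fell by 5.10 ± 0.24, Cyp2d13 by 4.77 ± 0.20, Wfdc21 from 13.09 ± 0.11 to 8.76 ± 0.84, and Slco2b1 by 4.0 ± 0.20. Serpina4-ps1 and Ugt2b38 fell at least 40.5-fold and 12.5-fold, to within background in KO. Probes of the major urinary protein and Cyp2 families can bind near-identical relatives, so their values may include more than the gene named.

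Pooled over 7 other cell types, 117 markers had a median difference of -0.099, and the 91 above background had -0.099, which turned to 0.41 with the arrays centred on the bacterial controls. Endothelial genes were lower in 8 of 18 and higher in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0155, and adjusted p = 0.545 with an estimated correlation), their median of -0.28 turning to 0.23 with the arrays centred on the bacterial controls. The call was lost without WT replicate 1 (adjusted p = 0.0757, from 0.00149 to 0.545 over 18 alternatives). Lyve1, a marker of sinusoidal endothelium, went the other way and rose at least 3.55-fold. Of 24 Kupffer cell and macrophage genes 3 were higher, namely Cd9 (1.36 ± 0.18), Lgals3 (1.26 ± 0.26) and Gpnmb, from 4.79 ± 0.45 in WT, a mean under background, to 6.96 ± 0.71, and camera did not pass (adjusted p = 0.911), with a median of -0.11 and a mean of 0.13. Stellate cell and fibrosis genes were higher in 2 of 27 and lower in 4 (2 and 6 adjusted over the list alone, camera adjusted p = 0.452), with the basement membrane collagen Col4a1 up 2.07-fold and Timp2 down 1.79-fold. Biliary and progenitor genes were higher in 3 of 13 and lower in 2 (camera adjusted p = 0.608), and Prom1 rose at least 2.44-fold. None of 17 T and NK cell genes passed in limma, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.452). Thy1 was within background in KO, at 4.65 ± 0.20 against 5.02 ± 0.10 in WT. Cd4 differed by -0.35 and passed without WT replicate 1 (-0.49, adjusted p = 0.0253, from 0.0208 to 0.323 over 15 alternatives). Of 8 B cell genes 1 was higher, Jchain (1.69 ± 0.38, camera adjusted p = 0.911), with a list median of -0.053 and mean of 0.16. Of 10 neutrophil genes 2 were lower (none adjusted over the list alone, camera adjusted p = 0.448). Camera also did not pass for erythroid cells (1 of 10 lower, none adjusted over the list alone, adjusted p = 0.911), adipocytes (2 of 8 higher and 1 lower, 0.778, with a median of -0.19 and a mean of 0.031) or pancreatic acinar cells (2 of 10 lower, 0.25).

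Further lists did not pass camera. Ketone body genes were higher in 2 of 6 and lower in 1 (adjusted p = 0.7), the fall being that of Bdh2 (-1.83 ± 0.20). Insulin signalling genes were higher in 5 of 19 and lower in 3 (5 and 4 adjusted over the list alone, camera adjusted p = 0.911), with a median of -0.074 and a mean of 0.21. Grb10, an adaptor that restrains the insulin receptor, rose by 2.31 ± 0.18, and the growth factor Igf1 was lower (-0.65 ± 0.10), a call lost with the arrays centred on the bacterial controls (-0.14, adjusted p = 0.257). Circadian clock genes were higher in 1 of 21 and lower in 2 (none and 1 adjusted over the list alone, camera adjusted p = 0.216, from 2.26e-08 to 0.766 over 18 alternatives, and 0.00519 without WT replicate 1). Cry2, a repressor of the clock, was lower (-0.80 ± 0.13), a call lost with the arrays centred on the bacterial controls (-0.29, adjusted p = 0.0856). Immediate early genes were higher in 3 of 20 and lower in 3 (3 and 4 adjusted over the list alone, camera adjusted p = 0.837), with a median of -0.12 and a mean of 0.042. Interferon-induced genes were lower in 6 of 21 and higher in 2 (camera adjusted p = 0.075, from 1.4e-05 to 0.78), and the list passed as lower without WT replicate 3 (0.00606) or KO replicate 3 (0.00465). The immunoproteasome subunits Psmb8 and Psmb9 were lower (-1.66 ± 0.20 and -1.36 ± 0.20) and the antiviral gene Rsad2 rose by 1.67 ± 0.32. Enzymes of arachidonic acid, sphingolipids and phospholipids were higher in 10 of 24 and lower in 4 (11 and 4 adjusted over the list alone), with Cyp2c23 lower (-1.83 ± 0.19) and Pla2g12a higher (1.21 ± 0.18). Camera gave an adjusted p of 0.0862, and 0.0337 without WT replicate 1. Over the alternatives the adjusted p ran from 0.0179, which was that of fry, to 0.635, that of camera with an estimated correlation. HIF-1 targets were higher in 2 of 15 and lower in 3 (3 and 5 adjusted over the list alone, camera adjusted p = 0.629), with Hif1a higher (0.68 ± 0.11) and Epas1 lower (-0.60 ± 0.10). The call of Hif1a was lost with the mean of its probe sets (0.23, adjusted p = 0.0804) and that of Epas1 with the arrays centred on the bacterial controls (-0.093, adjusted p = 0.399).

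Of the 51 lists, 19 passed camera with its preset correlation, 11 of them higher and 8 lower in KO, and 0 passed with camera's estimated correlation, where the lowest adjusted p was 0.113 and 9 lists had an unadjusted p under 0.05. Camera on ranks passed 20 lists and fry 25, but fry asks whether a list's genes move one way and not whether they differ from other genes. Splits of the 6 arrays that mix the genotypes gave up to 16 lists with the preset correlation and 0 changed genes, with at most 669 genes at an unadjusted p under 0.05. Each group of such a split holds more arrays of one genotype, so part of the difference between KO and WT remains between its groups. The rest widens the spread within them, so these counts are not a chance rate. The 21 genes fixed in advance that could be measured gave 12 calls, and 14 adjusted over the list alone, Pklr and Ppara being the additions. Of the 178 changed genes named by the rule in advance, 177 had all 3 KO arrays on one side of all 3 WT arrays, which the rule required of the largest 20 and which passing limma with 3 arrays against 3 favours in the others.

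**Figure D3:**
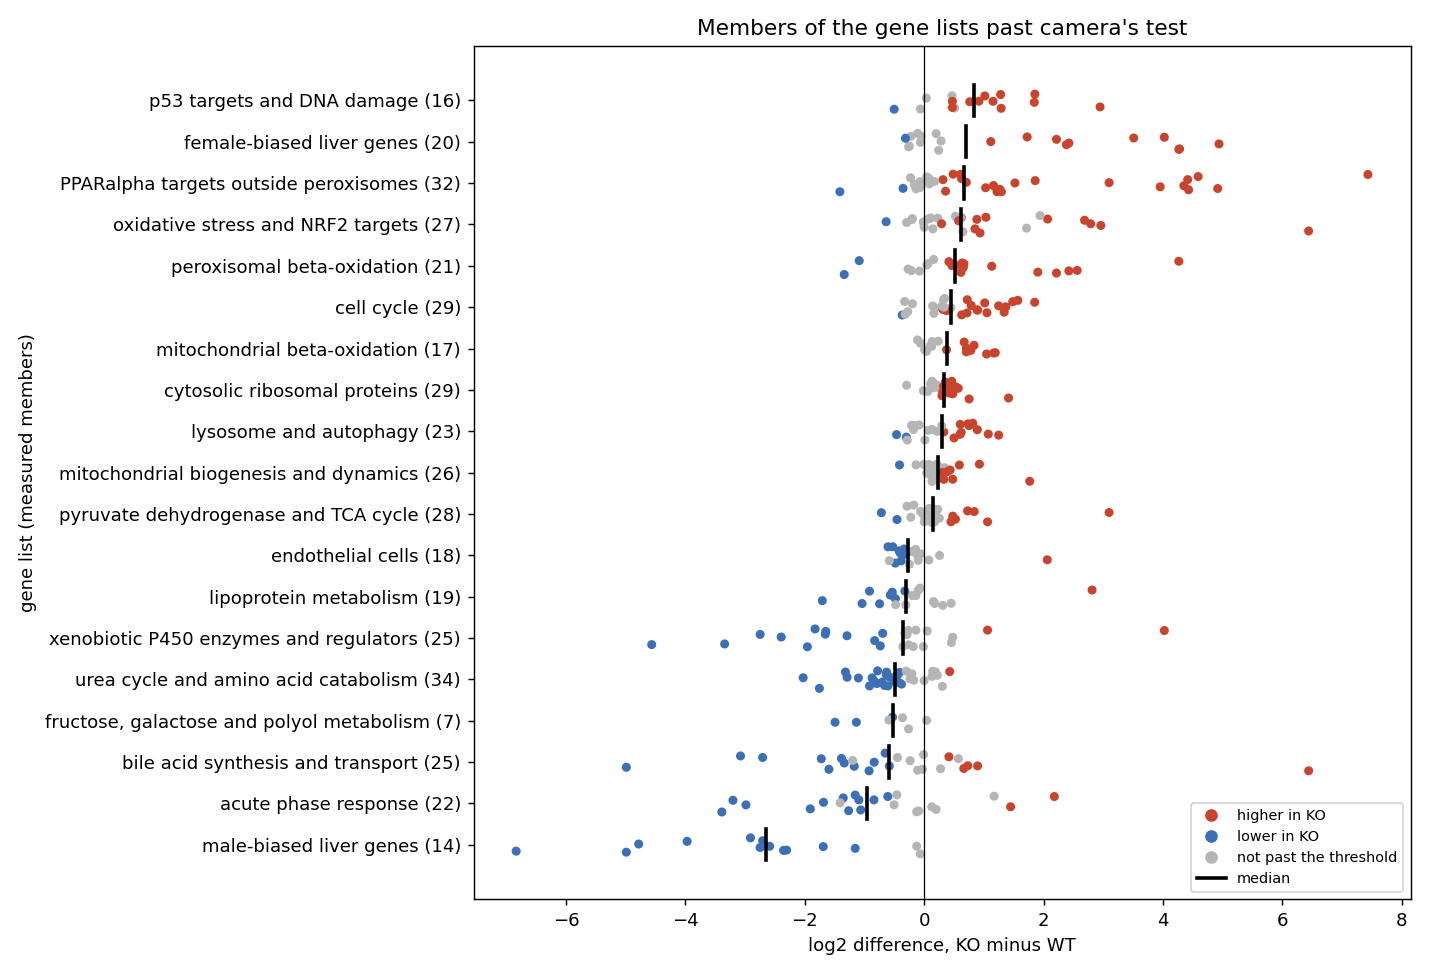
Log2 difference, KO minus WT (x axis), of each measured member of the 19 lists past camera's test with its preset correlation (y axis, number measured in brackets), with red for higher and blue for lower genes and a black bar for the median. Medians run from -2.65 for male-biased genes to 0.84 for p53 targets, and those of the endothelial, lipoprotein, xenobiotic and urea cycle lists turn positive with the arrays centred on the bacterial controls.

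Among the transcripts added as controls, the hybridisation controls (14 probe sets, with cre counted apart) stood at 9.89 ± 0.09 on WT and 9.46 ± 0.03 on KO arrays. The poly(A) controls stood at 9.86 ± 0.12 and 9.30 ± 0.10. In both sets the groups did not overlap, and the exact two-sided permutation p of 0.1 is the smallest that 3 arrays against 3 can give. The bright cre control differed by -0.072 and the trp control, near background, by -0.011. The 3' minus 5' difference of actin, a sign of RNA integrity, was 0.89 ± 0.06 in WT and 0.85 ± 0.04 in KO (exact permutation p = 0.5). That of Gapdh was 0.014 ± 0.018 in WT and -0.075 ± 0.028 in KO, without overlap between the groups (exact permutation p = 0.1).

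**Figure D4:**
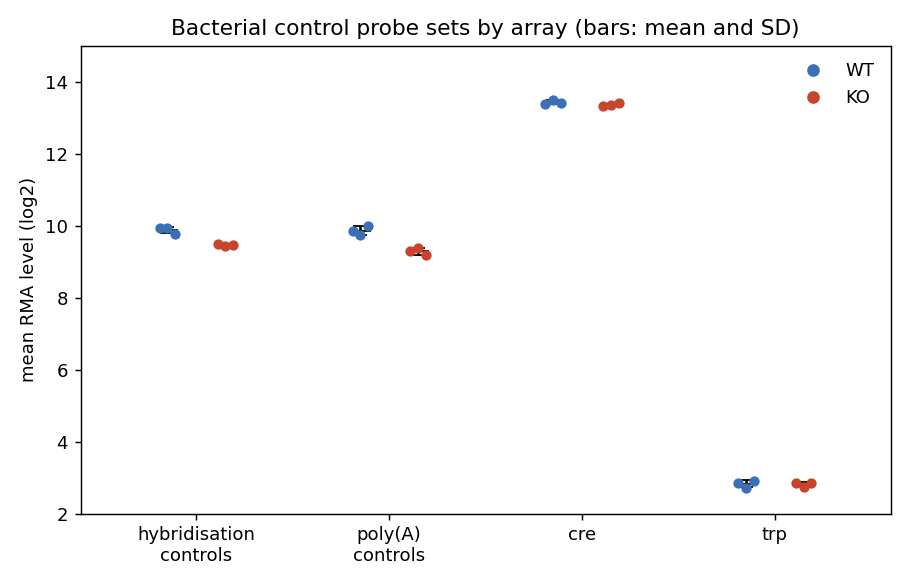
Mean RMA level (log2, y axis) of the 4 kinds of bacterial or phage control probe sets (x axis) on 3 WT and 3 KO arrays, with points for arrays and bars for mean and SD. The hybridisation and poly(A) controls are lower on the KO arrays by 0.42 and 0.56, a gap that centring the arrays on these controls removes by construction.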

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

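The tests on control transcripts and on the urea cycle list were chosen only after the result was seen. The tests on sex-biased genes were written before.

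Among the 10092 probe sets that carry no single gene name and enter none of the gene counts, 399 were higher and 449 lower in KO than in WT (limma over all probe sets other than controls, adjusted p under 0.05). They were looked at again because they hold signal outside the gene comparison. The probe set with the largest rise went from 3.24 in WT, under the background of 4.90, to 9.27 in KO (adjusted p = 3.45e-06), so the size of its rise is not fixed. No explanation was tested.

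Male-biased genes were lower and female-biased genes higher in KO livers, with medians of -2.65 and 0.70. A mix-up with female animals would raise Xist and remove the Y-linked transcripts, but Xist differed by 0.09 ± 0.10 and the 3 measured Y-linked genes, Eif2s3y, Kdm5d and Uty, had a median difference of 0.62. A general loss of bright hepatocyte transcripts was predicted to leave the male-biased median of -2.65 inside the range of 10000 random lists matched on level. Their central 95% ran from -0.19 to 0.28, and the female-biased median lay above its own range (-0.17 to 0.15). The male-biased list thus fell further than genes of its level. The random lists were drawn from all genes and not from hepatocyte genes, so they cannot exclude a loss of hepatocyte transcripts. The hepatocyte identity list had a median of -0.21 against this -2.65, and of 20 female-biased genes 10 were higher and 1 lower. A general loss of hepatocyte transcripts would not raise the female-biased genes, so these values argue against it as the cause of both changes. Whether such a loss adds to the fall of the male-biased genes is left open. A mix-up with female animals is argued against. The genotype, which the design names, may remain as an explanation that was not tested.

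The bacterial hybridisation and poly(A) control transcripts were lower on the KO arrays, 38 of 38 probe sets, with a median of -0.52. The 4 probe sets of the bright cre control, counted apart from the hybridisation controls here, and the trp control near background are not among these 38. They differed by only -0.072 and -0.011, so not all added controls fell alike. If KO livers held more messenger RNA per unit of total RNA, the poly(A) controls added to total RNA would fall and the later hybridisation controls would not, but the fall of the hybridisation controls was 0.75 of that of the poly(A) controls. If the normalization pushed down all probe sets of that brightness, genes between the controls' quartiles (8.56 to 10.32) would fall with them. The median of these 2390 genes was 0.12, but RMA forces the arrays towards one distribution and holds such medians near 0. That value therefore cannot tell whether the normalization lowered the controls. A difference in how much labelled RNA or control mix went onto the arrays of each group may remain, and so may an effect of the normalization. Neither can be separated from genotype because the sources used here give no hybridisation batch. Of the 1774 genes lower as deposited, 409 were called lower with the arrays centred on the controls, which adds 0.51 to all genes.

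Urea cycle and amino acid catabolism genes were lower in KO livers, with a median of -0.49 (bootstrap 95% interval -0.66 to -0.30), which turned to 0.02 with the arrays centred on the bacterial controls. A smaller share of hepatocytes would raise the markers of the other cell types. The 117 markers of 7 other cell types had a median of -0.099 (interval -0.18 to -0.058). The 91 of them above background gave -0.099 (-0.18 to -0.039) as deposited and 0.41 with control centring, under the 0.46 of all genes. These intervals, like that of the urea cycle list, resample genes and not livers. They do not measure the spread between animals, so the medians show no rise relative to the bulk of genes but do not exclude a smaller share. For a fall shared by genes of the same level, matched random lists had a central 95% from -0.16 to 0.20 against the list's -0.492. Camera had already placed the list below other genes on these arrays, and RMA holds genes of any level near 0. The comparison therefore adds no separate evidence and cannot exclude a fall shared by hepatocyte genes. Lower transcription of these genes in hepatocytes may remain as a hypothesis relative to the bulk of genes, with the overall scale left open by the control transcripts.

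The real grouping gave 4363 changed genes, and the highest of the other 9 splits of the 6 arrays gave 0. It gave 19 gene lists, and the others gave from 6 to 16. In each case 1 of 10 splits reached the real value, and 10 splits are too few for a share under 0.05. The other splits also keep part of the difference between KO and WT and widen the spread within groups, so their counts are not a chance rate.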

How the results depend on the processing

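Centring on the bacterial controls was chosen after seeing the data. Counts of 4363 changed, 2589 higher and 1774 lower genes stayed within 1.5 times under the 7 alternatives of filter, normalization, probe set choice, eBayes options and array weights, from 3983 to 4853 changed. Leaving out each array in turn gave 2385 to 4103 changed, 1497 to 2424 higher and 888 to 1679 lower genes, with fewer arrays as the known difference. An adjusted p of 0.01 gave 2017 (1285 higher, 732 lower), a 1.5-fold minimum 2196 (1422 and 774) and limma's treat against 1.2-fold 1593 (1012 and 581), since each asks for more. Control centring gave 13379 (12970 and 409), 3000 of them among the 4363, since it adds 0.51 to all genes. Lists past camera fell from 19 to 0 with an estimated correlation, were 20 by ranks and 25 by fry.

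Among named genes with a call on either scale, those reversed under control centring, by that same shift, were Prkag1 (0.37), Prkag2 (0.39), Srebf2 (0.025), Pfkm (0.047), Ndufa3 (0.14), Sirt3 (0.032), Fgb (0.022), Hlf (0.009), Ngp (0.076), Csf3r (0.12), Tek (0.03), Fech (0.18) and Bnip3 (0.051). Ppara, Ppargc1b, Pklr, Thy1 and Cd4, without a call on either scale, had falls smaller than the shift and so also change sign. Ndufs4 turned to -0.24 with the mean of its probe sets, and the cause was not tested. Of 189 named genes, 31 lost their call without KO replicate 2 and 27 without KO replicate 1.

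Same-numbered WT and KO arrays deviated together at r of 0.105, -0.018 and 0.105, and KO replicate 2 correlated best with WT replicate 1 (0.116). With 3 arrays per group these values cannot tell whether the numbers pair the livers. The replicate block gave 4089 changed genes and 18 lists, and called G6pc lower (adjusted p = 0.0256) and Prkaa1 no longer (0.0503). Array weights gave WT replicate 3 the least weight (0.375). Genes near the background of 4.90 have bounded falls.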

Other observations

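The lists and their tests in the first 2 paragraphs were chosen only after the result was seen, and part of each list's members were picked because they stood out, so the tests describe these arrays and are not independent evidence. The chromosome test was written before.

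One list held targets of the transcription factor ATF4, stress regulators among them, with enzymes of serine and one-carbon metabolism. Of its 37 measured genes 21 were higher, 1 was lower and 15 were not called, with a median of 0.95 (camera adjusted p = 8.96e-11 over these 4 lists, and adjusted p = 0.0223 with an estimated correlation). Slc3a2, a subunit of amino acid exchangers, rose 6.26-fold, Ddit4, an inhibitor of mTORC1, 8.87-fold, the arginine carrier Slc7a1 2.98-fold and the glycyl-tRNA synthetase Gars 2.55-fold. Asparagine synthetase, Asns, differed by 2.24 ± 0.82 without a call (adjusted p = 0.0835), and Shmt2, a mitochondrial one-carbon enzyme, fell by 0.94 ± 0.11.

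Complement and coagulation factors, which hepatocytes secrete, were lower in 26 of 32 genes and higher in 1, with a median of -0.88 (camera adjusted p = 4.56e-15, and adjusted p = 0.071 with an estimated correlation). C9, C8a and F11 fell 15.52-fold, 6.72-fold and 4.40-fold, and Serpinc1, antithrombin, differed by 0.009 ± 0.08. Among 26 carriers of organic anions, cations and bile salts 7 were higher and 10 lower (camera adjusted p = 0.22), with the anion carrier Slc22a7 down 15.56-fold and the bile salt carrier Slc10a1 3.30-fold. Of 20 genes of thyroid and growth hormone signalling 7 were lower and 2 higher (camera adjusted p = 0.00903, and adjusted p = 0.212 with an estimated correlation), their median of -0.48 lying within the 0.51 that control centring adds, and the growth hormone receptor Ghr fell by 0.76 ± 0.10. The deiodinase Dio1 fell at least 4.75-fold, to within background in KO.

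A hypothesis was that sequence of the strain in which Pex5 was targeted may alter genes around it. Of the 100 tested genes on each side of Pex5, 51 of 200 were changed (25.5%), against 24.0% of all other genes, a ratio of 1.06 (one-sided Fisher exact p = 0.332), which argues against a cluster of changed genes there. The order of genes was taken from the assembly GRCm38.p6.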
